A study of Arabidopsis thaliana with 12 samples.

How the data were processed

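Total RNA of whole Arabidopsis thaliana seedlings was measured on 12 one-colour Agilent arrays, 3 for each of 4 genotypes, with Cy3-labelled cRNA per the labels' protocols. Samples were grouped by the genotype in the labels, and the series design describes the 3 samples of a genotype as independent biological samples. The seedlings were 10 days old.

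The deposited scanner files hold the spot intensity on a linear scale. Per the file headers, the processed intensity was background-subtracted and detrended within each array by Agilent Feature Extraction, and spots at background carry surrogate values. The submitters' processing notes name Agilent Feature Extraction 10.7.3.1. The headers record no scaling between arrays. The values deposited for the series held the same intensity values as the scanner files, with 0 cells that differed, so it gave no separate alternative.

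Each of the 45220 spots per array was taken from the scanner files. Control spots and spots flagged as outliers were left out, spots of 1 probe were averaged, and the log2 of the deposited processed intensity minus the 75th percentile of the array was analysed. Of 43603 probes, 34285 carried a locus identifier (25383 loci) and 9318 did not. Symbols were taken through the locus identifier from an annotation table of assembly TAIR10.1. The array design is older, so no coordinates are given. A gene was represented by the probe with the highest mean over all 12 arrays, and 6919 genes had several probes. A probe was tested when it was well above background on all 3 arrays of at least 1 genotype and had at least 2 values in each genotype, which left 19020 genes. The number of arrays sets the precision, with 8 residual degrees of freedom. After removal of outlier spots 756 values were missing in 647 genes. A removed spot counts as not well above background. The missing values were replaced by the genotype mean for the list tests and the principal components only.

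One linear model with a mean per genotype was fitted over the 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with data.table for input (version 1.17.8). Every adjusted p for a gene comes from limma's moderated test with Benjamini-Hochberg adjustment over the tested genes of that comparison, and 0.05 was the threshold. The ± values are standard errors. The comparisons were arf2 with WT, gnc gnl with WT, the libraries labelled arf2 gnc gnl with each other genotype, the interaction of both mutations, and a moderated F test over the genotypes. Figures were drawn with matplotlib 3.10.9. Where a gene was not well above background on any array of 1 group, its fold is a bound, written as at least N-fold. The mean of the brighter group was then set against, per array of the dimmer group, the higher of the lowest signal among probes well above background and the probe's own signal. No fold is given where that bound is under 1 or both groups were dim.

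Before the data were examined, the tests, the rule for named genes, 38 gene lists of pathways and tissue markers, and the alternatives were fixed, apart from those named as chosen later. Named genes were ARF2, GNC and GNL. In each of the 3 main comparisons they also included the 6 genes with the largest change each way among those past the threshold whose arrays did not overlap between the groups, and 3 each way elsewhere. "Largest" refers to that rule. Up to 4 members with the smallest p were named from the 8 lists with the smallest p, and members of other lists were named after their values were seen. Of 685 members written, 678 were on the array and 637 were tested. For 17 the reference lacked the symbol. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the 38 lists of a comparison, and again with an estimated correlation. The fry test, which asks whether the genes of a list move on balance in 1 direction, was run beside it.

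Slide numbers came from the scanner files, and each slide was scanned as 1 batch. Slide was fitted as a fixed and as a random block, and the 3 comparisons with both groups on 1 slide were also fitted within it. Correlations between comparisons were set against simulated unchanged groups, and overlaps against the count for independent lists.

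The other alternatives were quantile normalization, median scaling, a normexp background correction (offset 50), no filter and a stricter filter on dim probes, outlier spots kept, the mean of all probes, each probe as a feature, the replicate number as a block, only the groups compared, an intensity trend, array quality weights, a log2 change of at least 1, and leaving out each array. The mean spot signal planned for normexp was not among the columns used here, so the median spot signal took its place. After the data were examined, fits were added without the libraries labelled arf2 gnc gnl, with the mean of the seed list as a covariate, with slide as a random block for all comparisons, within slides, and with replicate numbers as pairs in the labelled libraries and gnc gnl. The labels do not say what a replicate number marks. Deviations from the group mean correlated above 0.1 for all 3 same-number pairs of these groups (0.132 to 0.347), but not for all pairs of any other groups. The method was tested on simulated data for arf2 against WT with 19020 genes, of which 200 changed. It recovered 66.7% of those changed 1.5-fold, 87.9% at 2-fold and 97.8% at 4-fold, and 4.99% of its calls were false.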

Results

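Transcript levels were measured in whole 10-day-old seedlings of Arabidopsis thaliana (accession Col-0), grown under long days without treatment, on 12 one-colour Agilent arrays. The 4 genotypes were wild type (WT), an arf2 mutant (arf2-8 in the labels), a gnc gnl double mutant and libraries labelled arf2-8 gnc gnl, written arf2 gnc gnl here. Each had 3 libraries, which the series design gives as independent biological samples, so n = 3 libraries per genotype holds below except where a removed outlier spot left 2 values. ARF2 encodes an auxin response factor, and GNC and GNL encode paired class B GATA transcription factors known for promoting greening. The 75th percentile of the array signal ran from 2051 (arf2 replicate 2) to 2864 (gnc gnl replicate 1), and 64.6% to 70.2% of the probes were well above background. Tests covered 19020 genes. The number of arrays limits the precision of every value. Across genes, the log2 levels of libraries of one genotype correlated at 0.989 to 0.996. The first principal component held 45.3% of the variance and ran from the gnc gnl libraries to the arf2 libraries. The second held 20.2% and set the WT libraries apart. The arrays lay on 3 slides of 4 arrays. Slide 1 held the 3 WT arrays and arf2 replicate 1, slide 2 held arf2 replicates 2 and 3 with replicates 1 and 2 labelled arf2 gnc gnl, and slide 3 held replicate 3 labelled arf2 gnc gnl with the 3 gnc gnl arrays.

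The genes named in the genotypes were read first in every library, since they check the labels. In the arf2 libraries, the ARF2 signal (AT5G62000) stood at 2.07%, 0.392% and 3.04% of the WT mean and was well above background in replicate 3 only. The log2 change from WT was -6.21 ± 0.56 (SE, limma, adjusted p = 1.37e-04). In the gnc gnl libraries, GNC (AT5G56860) stood at 4.41%, 5.89% and 3.92% of WT, a log2 change of -4.42 ± 0.13 (adjusted p = 5.11e-08). GNL (AT4G26150) was not well above background in any gnc gnl library and was at least 9.51-fold lower than in WT (adjusted p = 1.52e-05). In the 3 libraries labelled arf2 gnc gnl, GNC was also low, at 6.40%, 5.65% and 5.61% of WT. A second GNC probe read 2.77% of WT in gnc gnl and 6.52% in the libraries labelled arf2 gnc gnl, and on it the libraries of these groups did not overlap. ARF2, however, read 56.8%, 54.4% and 70.5% of WT in those libraries, a log2 level 5.48 ± 0.56 above the arf2 libraries (adjusted p = 0.00149). GNL read 168%, 180% and 180% of WT there, at least 16.7-fold above gnc gnl (adjusted p = 1.13e-05). Against WT neither passed the test, with log2 changes of -0.73 ± 0.56 for ARF2 (adjusted p = 0.507) and 0.81 ± 0.33 for GNL (adjusted p = 0.214). For both genes, however, the 3 labelled libraries did not overlap the 3 WT libraries. With slide as a block the ARF2 change was 0.080. No slide held both groups, so that value ran through the arf2 libraries, where ARF2 was near background, and cannot test the change. The standard errors pool the spread of all genotypes, which was widest where the gene was near background. For ARF2 the SD was 1.57 in arf2 and 0.064 in WT, and for GNL 0.88 in gnc gnl and 0.22 in WT. The ARF2 and GNL probes thus contradicted the label of these libraries. They are called the libraries labelled arf2 gnc gnl throughout, and every direction drawn from them rests on that label.

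**Figure D1:**
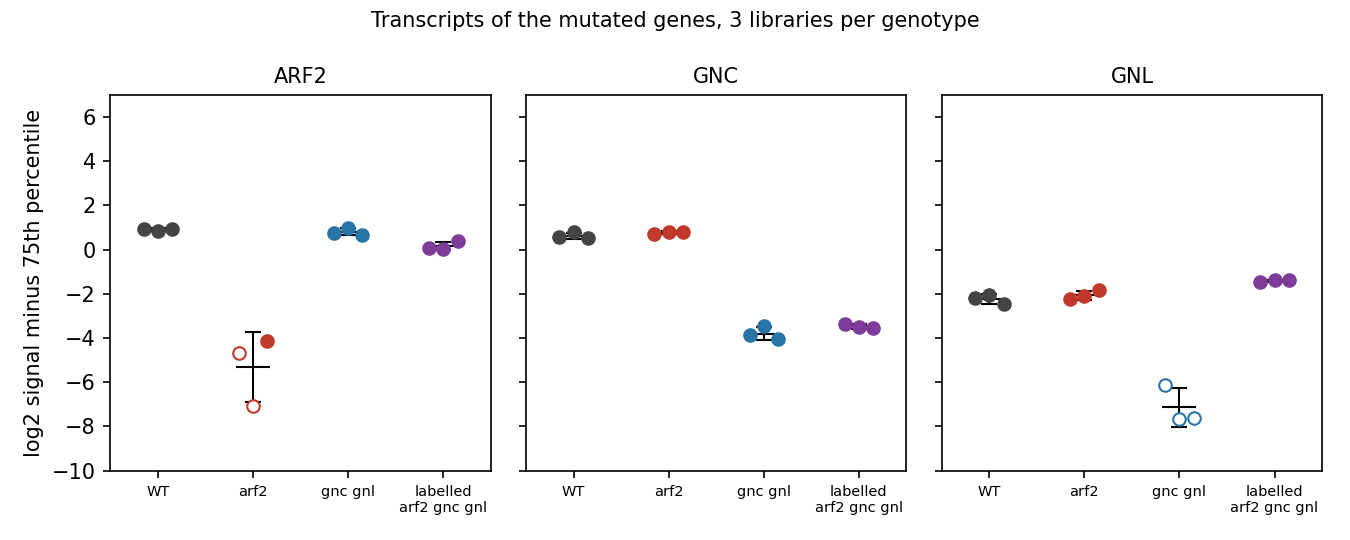
Log2 signal minus the 75th percentile of the array for ARF2, GNC and GNL, with 1 point per library (open where not well above background) and bars for the mean and SD of 3 libraries. In the libraries labelled arf2 gnc gnl, ARF2 averaged 60.2% and GNL 176% of WT, while GNC averaged 5.88%.

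The comparison of arf2 with WT asked what loss of ARF2 changed while GNC and GNL were intact. Seed transcripts showed the largest rises. CRU3 (AT4G28520), a cruciferin seed storage protein, rose 209-fold (log2 change 7.71 ± 0.92, adjusted p = 7.02e-04), and AT1G54870 rose 106-fold (6.73 ± 0.67), being well above background in 1 of 3 WT libraries. AT5G35660 rose by 6.08 ± 0.60 log2 units, and by 3.005 on its other probe. Against WT libraries in which they were not well above background, AT3G56350 rose at least 26.9-fold, the peroxygenase gene ATPXG2 (AT5G55240) at least 21.7-fold, and the 2S albumin gene SESA5 (AT5G54740) at least 18.4-fold. The largest falls included 2 genes of phosphate supply, the purple acid phosphatase PAP14 (AT2G46880, -2.76 ± 0.55) and the phosphatase PEPC1 (AT1G17710, -2.49 ± 0.54), with the pectin methylesterase gene ATPMEPCRD (AT2G43050, -2.46 ± 0.21). AT1G29090 fell at least 4.42-fold, AT5G64190 at least 2.17-fold, and CYP735A2 (AT1G67110), a cytokinin trans-hydroxylase, at least 1.71-fold. GNC and GNL did not pass the test in arf2, with log2 changes of 0.14 ± 0.13 (adjusted p = 0.648) and 0.17 ± 0.33 (adjusted p = 0.847). The second GNC probe stood at 99.7% of WT, and the GNL value was -0.0063 with slide as a block.

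A total of 1088 genes changed in arf2, 471 higher and 617 lower, of which 348 changed by 1 log2 unit or more. The share of higher genes, 43.29%, was 68.42% of 114 genes under normexp. It was 51.23% to 58.67% without WT replicate 1 or 3 or arf2 replicate 1 or 2, so the lower majority was not stable. Array quality weights called 5052 genes, of which 40.97% were higher. A fit with slide as a block, in which slide 1 alone compares these genotypes directly, called 451 genes, of which 366 were among the 1088. The arrays of slide 1 fitted by themselves gave 762, with no replicate in arf2, whose single array there was assumed to vary like the 3 WT arrays. Leaving out 1 library gave 450 genes without WT replicate 1, 523 without WT replicate 3, 527 without arf2 replicate 1 and 498 without arf2 replicate 2. In checks chosen after the data had been seen, 666 genes passed without the libraries labelled arf2 gnc gnl, and 283 with the mean of the seed list per array as a covariate.

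Of the 38 gene lists, 23 passed the list test in arf2 against WT (limma's camera with a preset correlation of 0.01), 11 upwards and 12 downwards. None passed with an estimated correlation, where the lowest adjusted p was 0.222. Of 13 seed markers, 8 rose and 5 did not pass (10 rose adjusted over the list alone), with a median log2 change of 4.49 (adjusted p = 1.55e-12, and adjusted p = 0.222 with an estimated correlation). Among them, the cruciferin CRA1 (AT5G44120) rose by 5.40 ± 0.69, the late embryogenesis protein EM6 (AT2G40170) by 2.85 ± 0.34, and ABI3 (AT3G24650), a regulator of seed maturation, at least 2.80-fold. The mean log2 level of the seed list lay between -1.01 and -0.60 in the arf2 libraries and between -5.02 and -4.07 in WT, so it differed between the groups in this comparison too. Of 21 abscisic acid and cold response genes, 6 rose and 15 did not pass (11 rose adjusted over the list alone, median 0.48, adjusted p = 1.21e-08, and adjusted p = 0.26 with an estimated correlation). The bZIP factor gene ABI5 (AT2G36270) rose by 2.18 ± 0.27, COR15B (AT2G42530) by 1.69 ± 0.38, AT5G66400, the dehydrin gene RAB18, by 1.28 ± 0.24 and KIN1 (AT5G15960) by 0.82 ± 0.21. Of 15 flavonoid genes, 9 rose and 6 did not pass (12 rose and 1 fell adjusted over the list alone, median 0.81, adjusted p = 1.60e-08, and adjusted p = 0.26 with an estimated correlation). MYB75 (AT1G56650), an activator of anthocyanin synthesis, rose by 2.12 ± 0.34, the flavonoid hydroxylase gene TT7 (AT5G07990) by 1.304 ± 0.14, FLS1 (AT5G08640) by 0.81 ± 0.14 and F3H (AT3G51240) by 0.79 ± 0.12.

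Phosphate starvation genes went the other way in arf2: 5 of 13 fell and 8 did not pass (11 fell adjusted over the list alone), with a median of -1.12 (adjusted p = 3.72e-08, and adjusted p = 0.26 with an estimated correlation). The 5 were the membrane lipid genes MGD2 (AT5G20410, -1.36 ± 0.27), SQD2 (AT5G01220, -1.15 ± 0.23) and PLDP2 (AT3G05630, -1.34 ± 0.33), with SPX2 (AT2G26660, -0.52 ± 0.09) and SPX3 (AT2G45130, -2.42 ± 0.62), the last named after its value was seen. Of 10 touch and rapid stress genes, 4 fell (9 adjusted over the list alone, median -0.58, adjusted p = 1.94e-07, and adjusted p = 0.222 with an estimated correlation). These were WRKY40 (AT1G80840, -1.14 ± 0.25), ZAT10 (AT1G27730, -0.74 ± 0.16), ZAT12 (AT5G59820, -0.64 ± 0.16) and SZF1 (AT3G55980, -0.45 ± 0.10, with 2 WT values after removal of an outlier spot). Of 21 auxin-responsive GH3 and SAUR genes, 2 fell, SAUR16 (AT4G38860, -0.43 ± 0.10) and SAUR62 (AT1G29430, -0.44 ± 0.12), 5 fell adjusted over the list alone, and the median was -0.28 (adjusted p = 3.93e-06, and adjusted p = 0.333 with an estimated correlation). All 21 light-harvesting genes lay above WT, at a median of 0.22 under the 75th percentile scaling (adjusted p = 3.72e-08, and adjusted p = 0.338 with an estimated correlation). Of these, LHCB4.3 (AT2G40100, 0.56 ± 0.09) and LHCB2.3 (AT3G27690, 0.49 ± 0.10) rose (6 genes adjusted over the list alone). Of 28 photosystem subunit genes none passed over all genes or adjusted over the list alone, while all 28 lay above WT at a median of 0.17 (adjusted p = 3.76e-06, and adjusted p = 0.447 with an estimated correlation). Examples were PSAE1 (AT4G28750, 0.29 ± 0.10, adjusted p = 0.146) and PSBO1 (AT5G66570, 0.28 ± 0.10, adjusted p = 0.131), the latter at -0.025 under quantile normalization, where the list test was lost (adjusted p = 0.165). Root markers also fell, with 3 of 19 called and 15 of 19 below WT (4 fell adjusted over the list alone, median -0.39, adjusted p = 6.09e-04, and adjusted p = 0.318 with an estimated correlation). The list medians with slide as a block, and equally within slide 1, were -0.16 for root markers, where the list did not pass with the block (adjusted p = 0.153), 4.70 for seed markers, 0.40 for abscisic acid and cold, 1.11 for flavonoids, -1.33 for phosphate, -0.66 for touch, -0.49 for GH3 and SAUR, 0.29 for light harvesting and 0.25 for photosystems.

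Gibberellin genes, a list fixed for the question, held 5 that rose among 25 in arf2 (7 rose and 1 fell adjusted over the list alone, list adjusted p = 0.00699, and adjusted p = 0.222 with an estimated correlation), named here after their values were seen. They were the biosynthesis genes GA20OX3 (AT5G07200, at least 3.299-fold), GA3OX1 (AT1G15550, 1.08 ± 0.13), GA3OX2 (AT1G80340, 0.65 ± 0.17) and GA3 (AT5G25900, 0.34 ± 0.06), and the DELLA gene RGL3 (AT5G17490, 0.39 ± 0.09). The flowering time list did not pass (3 up of 21, and 3 up and 3 down adjusted over the list alone, adjusted p = 0.205), though its repressors FLC (AT5G10140, 0.78 ± 0.09) and MAF4 (AT5G65070, 1.18 ± 0.18) and the AP2-type gene SNZ (AT2G39250, 0.63 ± 0.13) rose. Of 25 Aux/IAA repressors of auxin signalling, 2 rose and 3 fell (2 and 4 adjusted over the list alone, median -0.17, adjusted p = 0.00899, and adjusted p = 0.447 with an estimated correlation). With the mean of the seed list as a covariate the Aux/IAA list did not pass (median 0.023, list adjusted p = 0.734). Of 26 chlorophyll synthesis genes only AT1G44446, the chlorophyllide a oxygenase gene, rose (0.25 ± 0.07), and none passed adjusted over the list alone (median 0.13, adjusted p = 7.02e-04, and adjusted p = 0.486 with an estimated correlation). None of the 4 other class B GATA genes that were listed passed over all genes or adjusted over the list alone (list adjusted p = 0.131). For these lists the medians with slide as a block, and within slide 1, were -0.14 for the GATA genes, 0.24 for chlorophyll synthesis, -0.18 for Aux/IAA and 0.0050 for flowering time. For gibberellin the median was 0.093 with the block and 0.096 within slide 1.

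**Figure D2:**
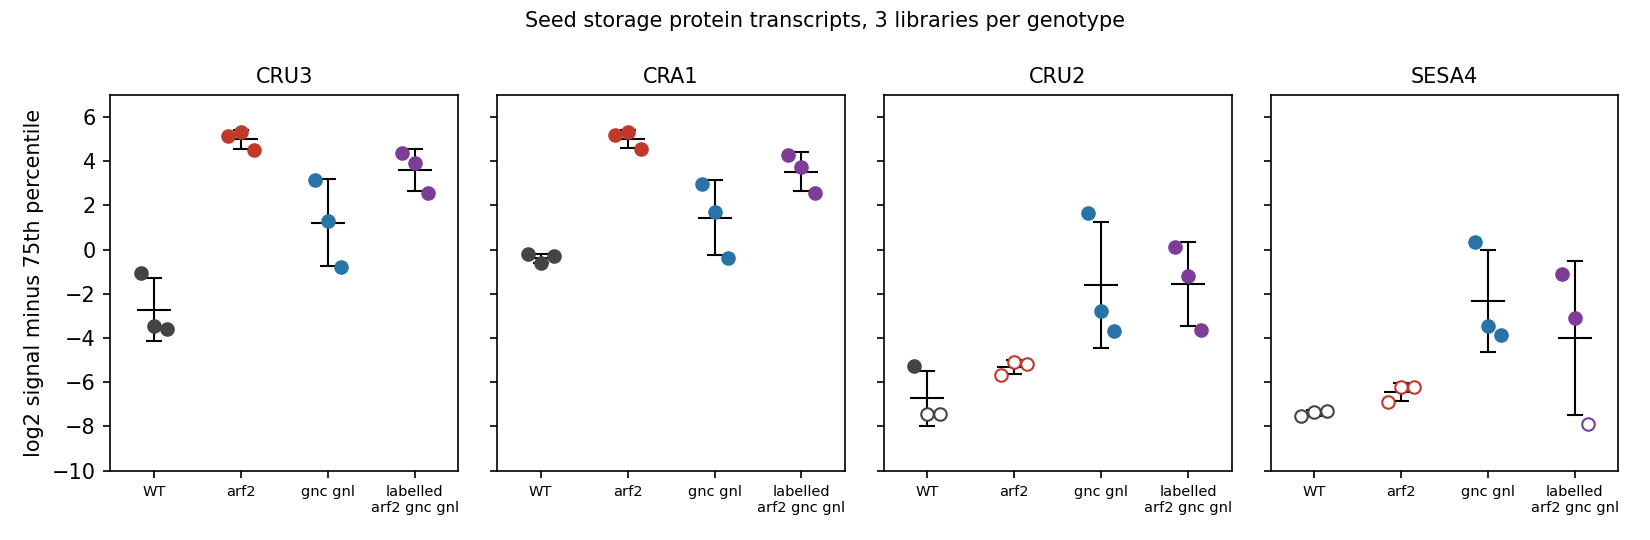
Log2 signal minus the 75th percentile of the array for 4 seed storage protein genes, with 1 point per library (open where not well above background) and bars for the mean and SD of 3 libraries. CRU3 averaged 4.99 in arf2 and -2.72 in WT, while CRU2 averaged -5.30 in arf2, where it was not well above background, and -1.59 in gnc gnl.

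The comparison of gnc gnl with WT asked what loss of both GATA factors changed while ARF2 was intact. Besides GNC and GNL, the largest falls were in AT1G13650 (-2.56 ± 0.16, adjusted p = 1.24e-05), UNE15 (AT4G13560, -2.56 ± 0.18) and the small heat shock protein gene HSP17.4 (AT3G46230, at least 1.83-fold lower). AT5G51610 (at least 3.01-fold), AT2G39590 (at least 2.95-fold) and ABCI9 (AT5G44316, at least 1.95-fold) also fell. Their log2 changes were 0.0019, 0.052 and 0.22 with slide as a block, which reads gnc gnl against WT only through the other genotypes. The largest rises were in seed storage genes with a wide spread between libraries. The 2S albumin gene SESA3 (AT4G27160) rose by 5.49 ± 1.63 and the cruciferin gene CRU2 (AT1G03880) by 5.14 ± 1.28, each well above background in 1 of 3 WT libraries. Their lowest probes read 3.31 for SESA3 and 3.73 for CRU2. SESA4 (AT4G27170) rose at least 7.60-fold, SESA2 (AT4G27150) at least 6.83-fold, SESA5 at least 5.54-fold, and PAP85 (AT3G22640), a vicilin-like protein gene, at least 8.47-fold. ARF2 itself did not pass, at -0.09 ± 0.56 (adjusted p = 0.925). Its log2 change of 0.49 with slide as a block ran through the arf2 libraries, where ARF2 was near background, and cannot test ARF2.

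Across all tested genes, 4686 changed in gnc gnl, 2380 higher and 2306 lower, and 428 of them changed by 1 log2 unit or more. No slide held both genotypes, so slide and genotype were linked only through arf2 replicate 1 on slide 1 and replicate 3 labelled arf2 gnc gnl on slide 3, and 29 genes passed with slide as a block, 27 of them among the 4686. With slide as a random block, a fit chosen after the data had been seen, 4248 passed, and the consensus correlation of arrays on a slide was 0.026. That correlation compares slides only within arf2 and the labelled libraries, since WT and gnc gnl each lay on a single slide. It cannot show whether slide accounts for the gnc gnl calls. Without WT replicate 2, 2376 genes passed. With the mean of the seed list per array as a covariate 2909 passed, and 4054 without the libraries labelled arf2 gnc gnl, checks chosen after the data had been seen.

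Of the 38 lists, 11 passed in gnc gnl, 7 upwards and 4 downwards, and none with an estimated correlation (lowest adjusted p = 0.234). Of 12 heat shock genes, 9 fell and 3 did not pass (9 fell and 1 rose adjusted over the list alone, median -0.67, adjusted p = 6.04e-05, and adjusted p = 0.29 with an estimated correlation). Heat shock genes were also lower than WT in arf2 (3 of 12 called, median -0.37, adjusted p = 4.29e-05, and adjusted p = 0.222 with an estimated correlation) and in the labelled libraries (4 of 12, median -0.41, adjusted p = 7.14e-07, and adjusted p = 0.317 with an estimated correlation). The touch list was lower than WT in the labelled libraries too (2 of 10, median -0.34, adjusted p = 1.85e-04, and adjusted p = 0.512 with an estimated correlation), and in gnc gnl it did not pass (3 of 10, median -0.30, adjusted p = 0.0986). These comparisons share the 3 WT arrays, so high values in WT alone would lower these lists in each. HSP17.6II (AT5G12020) fell at least 3.15-fold in gnc gnl. HSP17.8 (AT1G07400) changed by -0.90 ± 0.11 and the cytosolic chaperone gene HSP90.1 (AT5G52640) by -0.81 ± 0.09 (with 2 WT values after removal of an outlier spot), and its other probe by -0.71. Of 23 plastid ribosomal protein genes, 4 fell and 19 did not pass (2 fell adjusted over the list alone, median -0.27, adjusted p = 8.39e-04, and adjusted p = 0.756 with an estimated correlation). These were RPS1 (AT5G30510, -0.51 ± 0.10), PRPS5 (AT2G33800, -0.45 ± 0.12), AT2G43030 (-0.43 ± 0.14) and RPL10 (AT5G13510, -0.34 ± 0.11). Of 12 plastid division genes, 6 fell and 6 did not pass (7 fell adjusted over the list alone, median -0.23, adjusted p = 0.00291, and adjusted p = 0.717 with an estimated correlation). Among them were MINE1 (AT1G69390, -0.45 ± 0.11, with 2 WT values after removal of an outlier spot), PDV2 (AT2G16070, -0.35 ± 0.08), MIND1 (AT5G24020, -0.33 ± 0.10) and CDP1 (AT3G19180, -0.30 ± 0.08).

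Cell wall growth genes, the expansins and xyloglucan endotransglucosylases, rose in gnc gnl in 10 of 24 cases, fell in 1 and did not pass in 13 (10 and 1 adjusted over the list alone, median 0.31, adjusted p = 0.00103, and adjusted p = 0.234 with an estimated correlation). XTH33 (AT1G10550) rose by 2.01 ± 0.25, XTH15 (AT4G14130) by 1.62 ± 0.17, XTH19 (AT4G30290) by 1.05 ± 0.14 and XTH18 (AT4G30280) by 0.98 ± 0.09. Of 18 nitrogen genes, 9 rose and 9 did not pass (9 adjusted over the list alone, median 0.32, adjusted p = 0.00214, and adjusted p = 0.547 with an estimated correlation). Among them were the nitrate transporter gene NRT1.1 (AT1G12110, 0.69 ± 0.09), the glutamate dehydrogenase gene GDH2 (AT5G07440, 0.64 ± 0.10), UPM1 (AT5G40850, 0.63 ± 0.10) and G6PD3 (AT1G24280, 0.59 ± 0.10). Of 15 flavonoid genes, 9 rose (10 rose and 1 fell adjusted over the list alone, median 0.53, adjusted p = 0.00266, and adjusted p = 0.717 with an estimated correlation). These included MYB75 (1.82 ± 0.34), TT19 (AT5G17220, 1.43 ± 0.34), LDOX (AT4G22880, 1.31 ± 0.27) and the chalcone synthase gene TT4 (AT5G13930, 0.64 ± 0.14). The flavonoid list also lay above WT in the labelled libraries, with 2 of 15 called and a median of 0.55. Its adjusted p there was 5.67e-06 by camera, and 0.512 with an estimated correlation. Flavonoid changes in arf2, gnc gnl and the labelled libraries share the WT arrays, so low values in WT alone would raise this list in each. Of 19 root markers, 6 rose (7 adjusted over the list alone, median 0.35, adjusted p = 0.00266, and adjusted p = 0.717 with an estimated correlation). Among them were the root hair genes PRP3 (AT3G62680, 0.95 ± 0.28), ADF8 (AT4G00680, 0.79 ± 0.18) and COBL9 (AT5G49270, 0.70 ± 0.21). The endodermal regulator MYB36 (AT5G57620) read 0.45 ± 0.12 on its brighter probe and -0.17 on the other. Of 13 seed markers, 6 rose (9 adjusted over the list alone, median 2.55, adjusted p = 0.00414, and adjusted p = 0.717 with an estimated correlation), with CRU3 at 3.94 ± 0.92. The mean log2 level of the seed list was -0.42, -2.12 and -3.44 in the 3 gnc gnl libraries, so it differed from WT in this comparison too. Adding slide as a block gave list medians of -0.95 for heat shock, -0.23 for plastid ribosomes, -0.20 for plastid division and 0.59 for cell wall growth. The medians were 0.26 for nitrogen, whose call was lost (adjusted p = 0.382), 0.997 for flavonoids, 0.79 for root markers and 4.21 for seed markers. No slide held both genotypes. Every gnc gnl value against WT with slide as a block, here and elsewhere, was therefore built from differences that involve the arf2 and labelled libraries. Such a value carries their changes and the contradicted label, so it does not separate gnc gnl from slide.

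Of 26 chlorophyll synthesis genes, 4 fell and 1 rose in gnc gnl (the same counts adjusted over the list alone, median -0.14, adjusted p = 0.0231, and adjusted p = 0.873 with an estimated correlation), named here after their values were seen. The protochlorophyllide oxidoreductase genes PORA (AT5G54190, -2.17 ± 0.31) and PORC (AT1G03630, -0.66 ± 0.09) fell furthest, with CRD1 (AT3G56940, -0.29 ± 0.08) and AT1G44446 (-0.27 ± 0.07), and HEMA2 (AT1G09940, 0.33 ± 0.09) rose. The list call was lost without WT replicate 2 (adjusted p = 0.167), without gnc gnl replicate 2 (adjusted p = 0.168) and with slide as a block (median -0.11, adjusted p = 0.262). The light-harvesting list did not pass (median -0.07, adjusted p = 0.227, and a median of 0.031 with the normexp background correction). Nor did the gibberellin list (6 up and 4 down of 25, adjusted p = 0.356) or the flowering time list (4 up and 4 down of 21, adjusted p = 0.979). The Aux/IAA list (3 up and 3 down of 25, adjusted p = 0.693) and the GH3 and SAUR list (3 up and 3 down of 21, adjusted p = 0.552) did not pass either. The same held for the 4 other class B GATA genes that were listed (adjusted p = 0.179). For all of these lists the counts adjusted over the list alone were identical. Among these GATA genes, GATA15 (AT3G06740, 0.25 ± 0.08) and GATA16 (AT5G49300, at least 1.77-fold) rose.

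**Figure D3:**
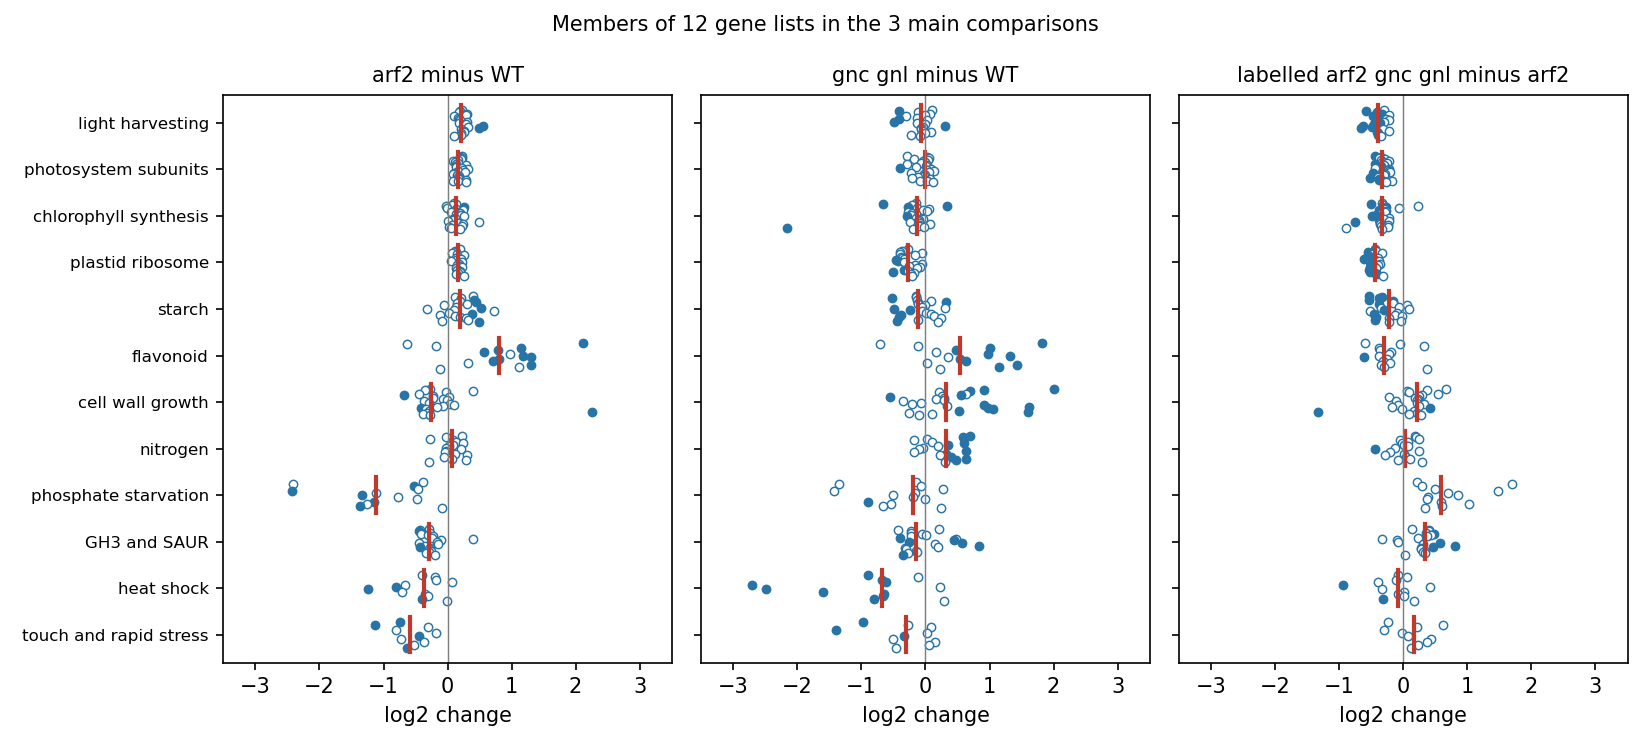
Log2 change of each tested member of 12 gene lists in the 3 main comparisons, with 1 point per gene (filled where its adjusted p was below 0.05) and red bars for list medians. For light harvesting the median was 0.22 in arf2 against WT and -0.39 in the libraries labelled arf2 gnc gnl against arf2.

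The comparison of the libraries labelled arf2 gnc gnl with arf2 was set up to read which arf2 changes need GNC and GNL, but since ARF2 and GNL were present in those libraries it does not isolate that loss. Genes of the chloroplast were lower in the labelled libraries in several lists. Of 23 plastid ribosomal protein genes, 14 fell and 9 did not pass (22 fell adjusted over the list alone, median -0.44, adjusted p = 4.94e-12, and adjusted p = 0.389 with an estimated correlation). RPL28 (AT2G33450) changed by -0.62 ± 0.15, RPL13 (AT1G78630) by -0.55 ± 0.13, RPL10 by -0.54 ± 0.11 and RPS1 by -0.52 ± 0.10. Of 21 light-harvesting genes, 13 fell and 8 did not pass (18 fell adjusted over the list alone, median -0.39, adjusted p = 5.24e-12, and adjusted p = 0.389 with an estimated correlation). Among them were LHCB2.3 (-0.66 ± 0.10), LHCB4.3 (-0.63 ± 0.09), LHCA6 (AT1G19150, -0.59 ± 0.12) and LHCB1.4 (AT2G34430, -0.46 ± 0.08). Of 28 photosystem subunit genes, 8 fell (21 adjusted over the list alone, median -0.34, adjusted p = 1.68e-11, and adjusted p = 0.389 with an estimated correlation). Among them were PSAL (AT4G12800, -0.53 ± 0.09), PSAH1 (AT3G16140, -0.48 ± 0.12), PETC (AT4G03280, -0.38 ± 0.09) and FD2 (AT1G60950, -0.35 ± 0.09).

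In the same comparison, 7 of 26 chlorophyll synthesis genes fell and 19 did not pass (21 fell and 1 rose adjusted over the list alone, median -0.33, adjusted p = 9.46e-10, and adjusted p = 0.389 with an estimated correlation). Among them were PORB (AT4G27440, -0.75 ± 0.16), PORC (-0.51 ± 0.09), CRD1 (-0.50 ± 0.08) and AT1G44446 (-0.27 ± 0.07). Of 20 Calvin cycle genes, 5 fell (19 adjusted over the list alone, median -0.33, adjusted p = 9.27e-10, and adjusted p = 0.389 with an estimated correlation). These were CP12-2 (AT3G62410, -0.46 ± 0.12), PRK (AT1G32060, -0.41 ± 0.10), FBA1 (AT2G21330, -0.40 ± 0.08), TKL1 (AT3G60750, -0.39 ± 0.07) and RPI3 (AT3G04790, -0.42 ± 0.12), the last named after its value was seen. Of 23 starch genes, 9 fell (10 adjusted over the list alone, median -0.23, adjusted p = 3.77e-07, and adjusted p = 0.389 with an estimated correlation). Among them were SBE2.1 (AT2G36390, -0.54 ± 0.11), PGM1 (AT5G51820, -0.44 ± 0.09), GBSS1 (AT1G32900, -0.39 ± 0.08) and AT1G11720, a starch synthase gene (-0.34 ± 0.07). Of 21 abscisic acid and cold genes, 4 fell (7 adjusted over the list alone, median -0.40, adjusted p = 2.57e-05, and adjusted p = 0.455 with an estimated correlation). These were COR15B (-1.94 ± 0.38), ABI5 (-1.20 ± 0.27), AT5G66400 (-0.94 ± 0.24) and NCED3 (AT3G14440, -0.85 ± 0.23), which acts in abscisic acid synthesis. Of 21 GH3 and SAUR genes, 4 rose (8 adjusted over the list alone, median 0.34, adjusted p = 1.32e-04, and adjusted p = 0.455 with an estimated correlation). These were SAUR15 (AT4G38850, 0.81 ± 0.19), SAUR9 (AT4G36110, 0.58 ± 0.13), SAUR64 (AT1G29450, 0.48 ± 0.13) and SAUR16 (0.46 ± 0.10). Of the 4 other class B GATA genes that were listed, 3 rose over all genes and adjusted over the list alone (median 0.47, adjusted p = 7.65e-04, and adjusted p = 0.389 with an estimated correlation). These were GATA15 (0.43 ± 0.08), GATA17 (AT3G16870, 0.52 ± 0.08) and GATA16 (at least 1.18-fold), named after their values were seen. The mean log2 level of the seed list was -0.02, -0.67 and -2.62 in the labelled libraries, and the seed list itself did not pass (1 down of 13, adjusted p = 0.137). Altogether 17 lists passed, 7 upwards and 10 downwards. The Aux/IAA list (2 up and 1 down of 25, adjusted p = 0.0531), the gibberellin list (3 down of 25, adjusted p = 0.0613) and the flowering time list (0 of 21, adjusted p = 0.0903) did not, and adjusted over the list alone their counts were 6 up and 1 down, 2 up and 3 down, and 0. Medians with slide as a block, and equally within slide 2, were -0.46 for plastid ribosomes, -0.38 for light harvesting, -0.33 for photosystems, -0.29 for chlorophyll synthesis, -0.36 for the Calvin cycle, -0.22 for starch, -0.41 for abscisic acid and cold, 0.22 for GH3 and SAUR and 0.47 for the GATA genes.

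The largest single rises over arf2, apart from ARF2, were in AT3G04210 (2.42 ± 0.43, well above background in 1 of 3 arf2 libraries), AT3G29970 (2.303 ± 0.45) and the MADS-box gene SEP3 (AT1G24260, 2.26 ± 0.24, well above background in 2 of 3 arf2 libraries), and, at least 3.172-fold, 1.97-fold and 1.76-fold, in AT1G29090, the mitochondrial import gene TIM17-1 (AT1G20350) and CYP735A2. The largest falls were in COR15B, the myrosinase-binding protein gene MBP1 (AT1G52040, -1.88 ± 0.14), AT5G45630 (-1.84 ± 0.33), AT3G53040 (-1.71 ± 0.42), AT3G05260 (-1.65 ± 0.40) and HSD6 (AT5G50770, at least 2.21-fold). GNC changed by -4.23 ± 0.13. In total 1667 genes changed, 811 higher and 856 lower, so 48.6% were higher, against 23.1% of 5009 without a filter on dim probes. With slide as a block 56 passed (54 of them among the 1667) and 17 within slide 2 (3676 at an unadjusted p below 0.05), GNC, AT3G29970, PAP14, AT1G13650 and MBP1 among them. Single libraries moved the count, which was 181 without arf2 replicate 1, 125 without arf2 replicate 2, 2803 without arf2 replicate 3, and 684, 155 and 481 without replicates 1, 2 and 3 labelled arf2 gnc gnl.

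Of the 1088 genes that changed in arf2, 411 (37.8%) also changed in the opposite direction in the libraries labelled arf2 gnc gnl against arf2, and 3 changed in the same direction. SEP3, SAUR16, LHCB2.3, LHCB4.3, COR15B and ABI5 were among the 411. Independent lists would share 47.5, a value that leaves out the shared arrays, and part of the excess may come from the shared arf2 libraries. The share was 16.1% without arf2 replicate 1, 13.5% without arf2 replicate 2, 61.9% without arf2 replicate 3, and 10.5% and 16.0% without replicates 2 and 3 labelled arf2 gnc gnl. Under slide as a block it was 6.43%. On arrays not used to choose the genes, the labelled libraries against gnc gnl, 351 of the 1088 changed in the same direction as in arf2 (63.6 for independent lists). The median ratio of the log2 changes in the 2 backgrounds was 0.374 (quartiles -0.03 and 0.67, 0.198 with slide as a block). Its denominator came from the arrays that chose the genes, so the choice of large changes lowers the ratio by itself. Across all tested genes, which are not independent replicates, the arf2 change correlated at 0.522 with the change of the labelled libraries from gnc gnl (covariance 0.0876). The gnc gnl change correlated at 0.348 with the change of the labelled libraries from arf2 (covariance 0.0429). The arf2 and gnc gnl changes, which share the WT arrays, correlated at 0.143, with a covariance of 0.0254 against 0.0135 simulated for unchanged groups. The simulated correlation was 0.506. It holds no real changes, which widen the spread and lower a correlation from shared arrays, so these correlations cannot be compared. Of the genes higher in arf2, 117 were also higher in gnc gnl (58.9 for independent lists), and of those lower in arf2, 115 were also lower in gnc gnl (74.8). In opposite directions, 134 were lower in arf2 and higher in gnc gnl (77.2), and 37 were higher in arf2 and lower in gnc gnl (57.1). The 3 WT libraries were too few to split, so part of the overlap in the same direction may come from the shared WT arrays. With slide as a block the arf2 and gnc gnl changes correlated at 0.464. The arf2 change correlated at 0.306 with the labelled libraries minus gnc gnl, and the gnc gnl change at 0.298 with the labelled libraries minus arf2. In that fit the gnc gnl change is a sum that contains arf2 minus WT and the labelled libraries minus arf2. The 0.464 and 0.298 thus set a change against a sum that contains it and cannot be compared with the values above.

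Against WT, the libraries labelled arf2 gnc gnl differed in 432 genes, 253 higher and 179 lower. CRU3 rose by 6.33 ± 0.92, SESA5 at least 17.59-fold and QQS (AT3G30720), a gene known for its part in starch and nitrogen allocation, at least 22.2-fold (adjusted p = 1.44e-06). HSP17.6II changed by -1.57 ± 0.27 (well above background in 2 of 3 labelled libraries) and HSP17.4 fell at least 1.92-fold, and GH9B15 (AT4G23560) passed but was not well above background in either group. Only 6 genes passed with slide as a block. Of the 38 lists 12 passed, and none with an estimated correlation (3 at an unadjusted p below 0.05, and 6 by fry). The count was 170, 125 and 215 without WT replicates 1, 2 and 3, and 184, 125 and 216 without replicates 1, 2 and 3 labelled arf2 gnc gnl. Against gnc gnl, 2202 genes changed, 1019 higher and 1183 lower, so 46.3% were higher, a share of 33.0% under median scaling. QQS (4.95 ± 0.24, well above background in 1 of 3 gnc gnl libraries), AT5G35660 (4.49 ± 0.60) and AT1G54870 (4.41 ± 0.67, 2 of 3 gnc gnl libraries) rose most, and GH9B15 (at least 5.16-fold), CYP96A5 (AT2G21910, -3.28 ± 0.47, 2 of 3 labelled libraries) and the polygalacturonase gene PGAZAT (AT2G41850, -3.27 ± 0.37, 1 of 3 labelled libraries) fell most. On its other probe AT5G35660 read 2.05. A fit with slide as a block called 174 genes, and within slide 3, with a single labelled array assumed to vary like the 3 gnc gnl arrays, only QQS did (limma, 1808 genes at an unadjusted p below 0.05). The count was 1355 without gnc gnl replicate 1, and 893 and 881 without replicates 1 and 2 labelled arf2 gnc gnl.

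The interaction asked whether the arf2 change differed between the background with GNC and GNL and the background labelled as lacking them. It passed in 502 genes, 296 with a positive and 206 with a negative difference, and in 116 with slide as a block. The largest positive differences outside ARF2 and GNL were in AT3G29970 (4.07 ± 0.64, adjusted p = 0.0121), PAP14 (3.43 ± 0.78, adjusted p = 0.0459) and SRO4 (AT3G47720, 3.32 ± 0.60, adjusted p = 0.0212). The largest negative ones were in SESA5 (-4.30 ± 0.69, adjusted p = 0.0131), AT5G46960 (-3.28 ± 0.31, adjusted p = 0.00108) and GH9B15 (-3.10 ± 0.33, adjusted p = 0.00193). These 3 values rest partly on signal at background. SESA5 was not well above background in WT, and AT5G46960 and GH9B15 were well above background in gnc gnl only. GNC did not pass (0.19 ± 0.19, adjusted p = 0.621, and -0.053 with the normexp background correction). Without 1 library the count was 205, 200 and 137 for WT replicates 1, 2 and 3, 197, 201 and 922 for arf2 replicates 1, 2 and 3, and 179 and 174 for replicates 1 and 2 labelled arf2 gnc gnl. Over all 4 genotypes, 6331 genes differed by the moderated F test, and 650 did with slide as a block.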

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

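The tests of probe position, label swap, mixed genotype, a single seed RNA source and the slide explanations were chosen only after the results were seen, as were the fits with the seed covariate and without the libraries labelled arf2 gnc gnl. In 502 genes the arf2 change differed between the 2 backgrounds by the interaction test, which drew attention to them. Among the named genes, the log2 difference was 5.565 for ARF2, 5.555 for GNL, 4.074 for AT3G29970, 3.425 for PAP14, 3.323 for SRO4, 2.536 for CYP735A2, 2.157 for HSP17.6II, 1.771 for HSP17.4, 1.734 for UNE15, 1.491 for SQD2, 1.139 for AT1G13650 and 0.8187 for HSP17.8. It was negative for XTH18 (-0.5685), F3H (-0.8297), LHCB4.3 (-0.9386), TT4 (-0.9534), TT7 (-0.9751), XTH19 (-1.07), LDOX (-1.698), XTH15 (-1.791), MYB75 (-2.413), CYP96A5 (-3.037), GH9B15 (-3.104), AT5G46960 (-3.278) and SESA5 (-4.296). Each rests on the contradicted label, and each includes the WT libraries, so values in WT alone could move it. GNL, CYP735A2, HSP17.6II, HSP17.4, GH9B15, AT5G46960 and SESA5 were not well above background in at least 1 genotype, so the size of their differences rests partly on signal at background. Probes without a locus, which the report does not use, also held signal, with 55 of 3297 higher and 45 lower in arf2 than in WT, and 249 higher and 486 lower in gnc gnl.

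The libraries labelled arf2 gnc gnl held ARF2 and GNL transcripts while GNC was low. Probes lying outside the altered part of the transcripts are argued against, since ARF2 fell in arf2 and GNL in gnc gnl on the same probes, and the smaller fall was 4.909 log2 units (GNL, at least 9.51-fold against background). A swap with another group of this series is argued against, since 0 of the 12 libraries had ARF2, GNC and GNL all more than 2 log2 units below WT. A harvest of mixed genotype at ARF2 may account for its level of 60.19% of WT, which lay between arf2 and WT in each of the 3 libraries. Lower transcription of an intact ARF2, a sample from outside the series and another gnl allele stay open, and no biological explanation was tested.

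Of 13 seed markers, 8 were called higher than WT in arf2, 6 in gnc gnl and 6 in the labelled libraries, and the others did not pass. In gnc gnl replicate 3, CRA1 (-0.36) and OLEO1 (-3.79) lay within the WT range. A single source of seed RNA of the same make-up in arf2 and gnc gnl is argued against, since the CRU2 minus CRU3 difference was 7.475 log2 units higher in gnc gnl than in arf2. CRU2 was not well above background in arf2, and raising it there to the lowest signal well above background left a difference of 7.08. The slide is argued against for arf2, since the seed list lay 4.695 log2 units above the WT arrays of the same slide in arf2 replicate 1, the only arf2 array on that slide. Seed coats or late seedlings in differing numbers, and an effect of the genotypes, may contribute and were not tested.

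The gnc gnl and WT arrays lay on different slides. The slide 3 minus slide 1 difference, read through arrays of the other genotypes and signed by the gnc gnl change, had a median of 8.676% of the median change of the called genes. That reading rests on single linking arrays, so slide and genotype cannot be told apart for these genes, and an effect of the genotype stays open.

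For each comparison of 3 arrays with 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10 gave as many genes in each. The real counts and the highest of the other splits were 1088 and 0 for arf2 with WT, 4686 and 0 for gnc gnl with WT, 432 and 0 for the labelled libraries with WT, 1667 and 0 with arf2, and 2202 and 2 with gnc gnl. For the interaction, 2 of 100 splits gave as many genes as the real 502, a share below 0.05. This excludes a grouping at random over all 12 arrays, but the splits mix genotypes that differ, so it does not exclude chance for the interaction itself. The highest other split gave 1634 genes. That split kept WT and gnc gnl whole and mixed arf2 with the labelled libraries. Its interaction thus set WT and gnc gnl against arf2 and the labelled libraries, which is a contrast of the real genotypes. For the F test, 1 of 100 splits reached 6331 genes, and the highest other gave 3472. These splits also mix genotypes that differ, and WT and gnc gnl each lay on a single slide. Only a grouping at random was thus excluded, not a slide difference.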

How the results depend on the processing

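The fits without the libraries labelled arf2 gnc gnl, with the seed covariate, with slide as a random block, with replicate pairs and within slides were chosen after the data were seen. Of the values for named genes and lists under the 29 settings whose values could differ, 5241 kept direction and side of the threshold, 738 kept direction but no longer passed, 46 newly passed and 26 reversed. Called genes that were not named are outside this tally. Of the 4686 gnc gnl calls, normexp kept 1982 and gave 278 the other sign, and slide as a block kept 27 and gave 208 the other sign. Of the 1667 calls of the labelled libraries with arf2, normexp kept 25 and gave 98 the other sign. A list counts as reversed by its camera direction against all other genes, and the value printed is its median. Signal over background limits the dim genes, and the cause of the shifts below was not tested unless named. Counts are in the order arf2 with WT, gnc gnl with WT, and the labelled libraries with WT, with arf2 and with gnc gnl.

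Normexp gave 114, 2189, 15, 25 and 299 genes, 21 interactions, 2231 by the F test, a share of opposite arf2 calls of 8.772%, a ratio of 0.5477, correlations of 0.4474, 0.5301 and 0.1876, and 6 lists in gnc gnl. Without a filter on dim probes the first count was 695, the last 3 were 222, 5009 and 1427, interactions 232, and correlations 0.3503 and 0.2859. Array weights gave 5052 for arf2, 1836 and 7270 for the labelled libraries with WT and arf2, 1959 interactions, 10552 by the F test, 64.89%, 0.2996 and a correlation of 0.0876. Slide as a block gave 451, 29, 6, 56 and 174, 116 interactions, 650 by the F test, 6.43%, 0.1983, and correlations of 0.306, 0.2978 and 0.464, in a fit where few arrays link the groups. The 0.2978 and 0.464 each set a change against a sum that contains it in that fit. Slide as a random block gave 1046, 4248, 355, 1653 and 1965. A log2 change of at least 1 gave 348, 428, 153, 159 and 313, fewer by construction. With only the groups compared the last 3 counts were 694, 1076 and 1149. Median scaling gave 965 with arf2. Probes above background on all arrays gave correlations of 0.4278, 0.3721 and 0.09895, and each probe as a feature 0.4857. The seed covariate gave 283 and 2909, 301 interactions, 0.4902, 0.3127 and 0.3418, and 7 lists in gnc gnl. Without the labelled libraries arf2 gave 666. Within slide 2 the count was 17, and within slide 3 it was 1, from fewer arrays. An estimated correlation left 0 lists in arf2, 0 in gnc gnl and 0 in the labelled libraries with arf2 by camera, while 6, 2 and 2 lists had an unadjusted p below 0.05 and fry called 17, 13 and 13.

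The share of higher genes moved by over 10 percentage points under normexp for arf2 (68.42%, against 43.29%) and for the labelled libraries with arf2 (28%, against 48.65%), where it was 23.12% without a filter on dim probes. It also moved for gnc gnl with slide as a block (20.69%, against 50.79%), for the labelled libraries with WT under array weights (47.33%, against 58.56%) and with gnc gnl under median scaling (32.96%, against 46.28%). Leaving out 1 array moved it as far. In arf2 the share was 58.67%, 56.02% and 54.22% without WT replicates 1 and 3 and arf2 replicate 2. For the labelled libraries with WT it was 72.8%, 72% and 71.76% without WT replicate 2 and labelled replicates 2 and 3. With arf2 it was 63.54%, 64% and 61.94% without arf2 replicates 1 and 2 and labelled replicate 2.

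Leaving out 1 array gave 450 to 1472, 2376 to 4860, 125 to 537, 125 to 2803 and 881 to 2394 genes, 137 to 922 interactions, 4223 to 6506 by the F test, 10.48% to 61.89%, a ratio of 0.2728 to 0.4475, correlations of 0.4688 to 0.5577, 0.3033 to 0.3882 and 0.0923 to 0.1769, and 21 to 26, 10 to 16 and 14 to 22 lists.

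These values reversed. With slide as a block, arf2 with WT gave -0.006276 for GNL and 0.005003 for the flowering time list. In gnc gnl the block gave 0.4949 for ARF2, 0.2231 for ABCI9, 0.001857 for AT5G51610, 0.05175 for AT2G39590, -0.08832 for Aux/IAA and -0.08438 for ethylene. In the labelled libraries with WT it gave 0.07963 for ARF2. No slide held WT arrays with gnc gnl or labelled arrays, so the block read these comparisons through the other genotypes. The ARF2 values among them ran through arf2 libraries near background and cannot test its change. With the seed covariate arf2 gave -0.002783 for GNC, -0.7717 for GNL, 0.02295 for Aux/IAA and 0.01728 for brassinosteroid. In gnc gnl it gave 0.199 for ARF2, -0.002034 for flowering time, 0.01882 for GH3 and SAUR and 0.09785 for light harvesting, and -0.05086 for GNL in the labelled libraries with WT. Quantile normalization gave -0.02507 for PSBO1 in arf2, and the mean of all probes 0.07937 for HSP90.1 in gnc gnl, by construction, since the brighter probe lacked 1 WT value and both probes fell (-0.8052 and -0.712). Normexp gave -0.05251 for the GNC interaction and 0.03091 for light harvesting in gnc gnl. For flowering time in gnc gnl, probes above background on all arrays gave -0.006742. Leaving out 1 array gave -0.1278 to 0.07707 for that list, with 0.06873 without WT replicate 3 and -0.01348 without arf2 replicate 3.

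The replicate block gave 1031, 4320, 375, 1415 and 2095 genes. Over all groups 7 of 18 same-number correlations were above 0.1 (range -0.367 to 0.369), so the numbers did not pair the samples throughout. For the labelled libraries with gnc gnl, where all 3 were above 0.1, these pairs as a block gave 2391 genes, 1984 of them among the 2202, and kept the call of every gene and list named for that comparison.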

Other observations

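The hypoxia test was written before its result was seen, and the genes named below outside the rule were chosen after their values were seen. Starch genes rose in arf2 in 5 of 23 cases, and 12 rose and 1 fell adjusted over the list alone. Their median was 0.20 and within slide 1 0.27 (adjusted p = 4.80e-06, and adjusted p = 0.26 with an estimated correlation). The disproportionating enzymes DPE1 (AT5G64860, 0.49 ± 0.11) and DPE2 (AT2G40840, 0.44 ± 0.08) were among them. Sulfate genes fell in 3 of 10 cases, and 7 fell adjusted over the list alone. Their median was -0.47 and within slide 1 -0.72 (adjusted p = 1.35e-05, and adjusted p = 0.26 with an estimated correlation). The 3 were LSU1 (AT3G49580, -0.90 ± 0.14), LSU2 (AT5G24660, -0.55 ± 0.12) and BGLU28 (AT2G44460, -1.28 ± 0.25). Cytokinin genes fell in 4 of 18 cases, and 4 fell adjusted over the list alone. Their median was -0.13 and within slide 1 -0.14 (adjusted p = 0.0186, and adjusted p = 0.26 with an estimated correlation). With slide as a block the list did not pass (adjusted p = 0.0543). The 4 were ARR3 (AT1G59940, -0.71 ± 0.17), ARR5 (AT3G48100, -0.61 ± 0.12), CKX1 (AT2G41510, -0.59 ± 0.12) and CKX4 (AT4G29740, -0.62 ± 0.16, well above background in 2 of 3 arf2 libraries). QQS, not well above background in WT, rose at least 13.0-fold in arf2 (adjusted p = 9.56e-06) and did not pass in gnc gnl (adjusted p = 0.199).

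Meristem and organ boundary markers rose in gnc gnl in 6 of 7 cases (6 adjusted over the list alone, median 0.36, adjusted p = 0.00706, and adjusted p = 0.547 with an estimated correlation), among them CUC1 (AT3G15170, 0.57 ± 0.17), CUC2 (AT5G53950, 0.57 ± 0.13) and KNAT6 (AT1G23380, 0.40 ± 0.09). The median was 0.25 with slide as a block, where the list did not pass (adjusted p = 0.217). In the libraries labelled arf2 gnc gnl, 9 of 19 root markers were lower than in gnc gnl, and 13 passed adjusted over the list alone. The median was -0.59 and within slide 3 -0.70 (adjusted p = 2.61e-06, and adjusted p = 0.384 with an estimated correlation). The root hair regulator RSL4 (AT1G27740, -1.06 ± 0.24) and COBL9 (-0.98 ± 0.21) were among them. In the same comparison 4 of 12 stomatal markers were higher, and 6 passed adjusted over the list alone. The median was 0.25 there and within slide 3 (adjusted p = 8.22e-04, and adjusted p = 0.47 with an estimated correlation). The 4 were EPFL9 (AT4G12970, 0.76 ± 0.10), KAT1 (AT5G46240, 0.66 ± 0.10), SLAC1 (AT1G12480, 0.54 ± 0.10) and FAMA (AT3G24140, 0.37 ± 0.09). Seed markers were higher against gnc gnl too, with 2 of 13 called and a median of 0.77, and 0.44 within slide 3. Their adjusted p was 0.0184 by camera, and 0.832 with an estimated correlation.

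A shared low-oxygen response was tested as a hypothesis on 16 core hypoxia genes that had not been looked at. The idea came from hypoxia genes already seen lower in arf2, and the 16 were read on the same arrays. Their agreement is therefore not independent evidence. Their median log2 change in arf2 against WT was -0.8351 (camera p = 4.99e-08, and p = 0.12 with an estimated correlation), -0.83 within slide 1, and 15 of 16 lay below WT. Of these, PDC1 (-1.21 ± 0.30), SRO5 (-1.19 ± 0.23) and HUP54 (-1.20 ± 0.29) passed over all genes. In gnc gnl against WT the median was -0.616, with 14 of 16 below WT, 1 called higher and 5 lower (camera p = 0.00129, and p = 0.334 with an estimated correlation), and -0.354 with slide as a block. In the libraries labelled arf2 gnc gnl the median was 0.089 against WT, with 9 of 16 above WT and 0 called. Against arf2 it was 0.92, with 9 higher and 1 lower (camera p = 2.17e-07, and p = 0.136 with an estimated correlation). The values may reflect a higher low-oxygen response in the WT libraries and those labelled arf2 gnc gnl than in arf2 and gnc gnl, and a difference in handling between harvests stays open.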
